A study of Homo sapiens with 6 samples.

How the data were processed

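RNA-seq counts per gene were analysed for 6 samples of Huh7, an established human hepatocellular carcinoma cell line. Per the labels, 3 samples were control cells and 3 overexpressed HK1, the gene of hexokinase 1. Per the labels' protocols, RNA was extracted with TRIZOL and libraries were made with a stranded mRNA kit. How HK1 was introduced, and what the control cells received, is not given in the sources used here.

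The deposited values are raw counts per gene, made by the authors with featureCounts version 1.5.3 in paired mode over exons grouped by gene name, per the file headers. The annotation was GENCODE release 47, including patches, haplotypes and scaffolds, per the file headers. Trim Galore and Subread are named, with the build hg38, per the submitters' processing notes, where no version of these tools is stated. The command line recorded in the file header sets no strand option. By that record the counting did not use strand, and a gene and an antisense or overlapping partner cannot be told apart by strand. It also sets no option to count fragments that map to several places or that overlap several genes. Fragments in exons shared by overlapping genes, or in near-identical copies on alternate sequences, may therefore be missing from the counts, so that a low level of such a gene is not evidence of low expression. Of the 79172 gene names in the table, 4995 had exons on alternate sequences and 38023 were Ensembl identifiers without a symbol.

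All columns were tested to hold whole numbers of at least 0. Each column was matched to its sample by its title. No other columns of sample values were present.

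Library totals were 20071846, 17284217 and 16771835 counts for control replicates 1, 2 and 3, and 19607663, 20499397 and 20823072 for HK1-overexpressing replicates 1, 2 and 3. Counts were normalized by TMM, and genes were kept by the filterByExpr rule, which left 16734 genes. Levels are given as CPM, counts scaled to the library total times its TMM factor, computed from the deposited counts. Groups were compared with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood test with group as the only term and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are HK1-overexpressing over control, with edgeR's default prior count. Standard errors are the size of the unshrunken coefficient divided by the square root of the quasi-likelihood F statistic. They are approximate, and too small for a change as large as that of HK1. A test against a fold of 1.5 used glmTreat on the same fit. Intervals at 95% are exact and, like limits for a count of 0, cover counting error only, since fragments amplified by PCR are not independent molecules.

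Gene lists, 46 in all, and the rule for naming genes were fixed before the data were examined, as were the tests and alternatives, except the quality weights, the GC trend as an alternative and the tests of chromosomes 9 and 10, which were chosen after the data were seen. The lists held 1337 symbols, of which 76 were in more than 1 list and 1 had no match in the table. Lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and HK1 left out of the lists and the background. The same test with the correlation estimated for each list, and fry, were alternatives. Named genes were HK1 and its paralogs, and, among called genes with a mean CPM of at least 10 and no overlap between groups, the 8 largest rises and falls and the 4 of smallest p each way. For each list that was called or had 3 or more called members, up to 4 called members of smallest p were eligible, and for lists with fewer than 2 called, the best uncalled members as values. The lists of glycolysis, hexokinases, glucose and lactate transport, the pentose phosphate pathway and the hexosamine pathway were included whatever their result. Genes outside the rule are said to be so. Some genes that the rule names are not reported here.

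Alternatives were other size factors, library totals only, HK1 or mitochondrially encoded genes removed, no filter or a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, no robust dispersion, a replicate block, a gene length trend, another threshold or fold, and leaving out each replicate. Quality weights for libraries and a GC content trend were also run. GC content came from GENCODE release 29 by gene name and was found for 81.9% of tested genes. Genome sequence was not used here.

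The test was tried on simulated data drawn from the means and library sizes of this comparison. Changes were seeded only in genes with a control mean of at least 5 CPM, so recovery at lower levels was not tried. Of 50 genes seeded at each fold, among 16292 tested genes, edgeR recovered 56% at 1.25-fold, 94% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. There were 16 false calls, 8.12% of the calls, which is above the nominal 5%. In simulated lists of 40 genes, camera found the list shifted by -0.25 on the log2 scale and not the unshifted list. The simulated genes were drawn independently, with the same dispersion in both groups. The simulation therefore cannot show the error rate for correlated lists, such as the cytosolic ribosomal proteins (estimated correlation 0.762), or where control libraries vary more.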

Results

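Gene expression was measured by RNA-seq in Huh7 cells, with 3 control and 3 HK1-overexpressing libraries, to ask how overexpression of hexokinase 1 affects hepatocellular carcinoma cells. Libraries held between 16771835 and 20823072 counts. MT-CO1 was the most abundant gene in all 6, at 2.10% to 2.30% of counts, and mitochondrially encoded genes took 8.06% to 9.11%. Counts within each group differed by more than sampling noise, so all libraries were kept as separate samples. The chi-square per degree of freedom was 5.08 to 11.3 between control pairs and 1.58 to 2.28 between HK1-overexpressing pairs. The labels do not say that replicates came from separate cultures. P-values of single genes then measure only the spread between these samples, which may be technical. Those of camera with the preset correlation set a list against the other genes and do not measure that spread.

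HK1, which catalyses the first step of glucose use, was almost undetected in controls and abundant in HK1-overexpressing cells. It lies on chromosome 10 from 69269984 to 69401884 (hg38) and was counted over its exons. Raw counts were 13, 15 and 13 in controls and 9723, 10602 and 11101 in HK1-overexpressing libraries. The level was 0.774 ± 0.114 CPM in controls and 508.5 ± 18.0 CPM in overexpressing cells (SD, n = 3 each). The log2 fold change was 9.36 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.15e-17). Its standard error from the F statistic was 0.0927, which is too small, as DESeq2 and limma-voom gave 0.233 and 0.213. The ratio of pooled counts, scaled to library totals without TMM factors, was 680.9, with an exact 95% interval of 501.8 to 949.0. HKDC1, a paralog that adjoins HK1 on chromosome 10 from 69220332 to 69267552, rose from 16.9 ± 1.08 to 25.7 ± 0.307 CPM (SD, n = 3 each), a log2 change of 0.60 with a standard error of 0.0754 (edgeR adjusted p = 0.000191). No 100-base window of HK1 matched HKDC1 at 95% identity or more. HK2, the main hexokinase of many tumour cells, was at 89.3 ± 7.54 CPM in controls and 95.7 ± 2.93 CPM in overexpressing cells and did not pass (log2 0.10, edgeR adjusted p = 0.403). HK3 had a count of 0 in every library, which allows up to 0.144 to 0.179 CPM by library, scaled to library totals without TMM factors. Of 4 tested members of the hexokinase list without HK1, 1 rose and 0 fell, and 2 rose when adjusted over the list alone (camera adjusted p = 0.0187). That call was lost with an estimated correlation (adjusted p = 0.159). Without control replicate 2, 2 members rose.

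**Figure D1:**
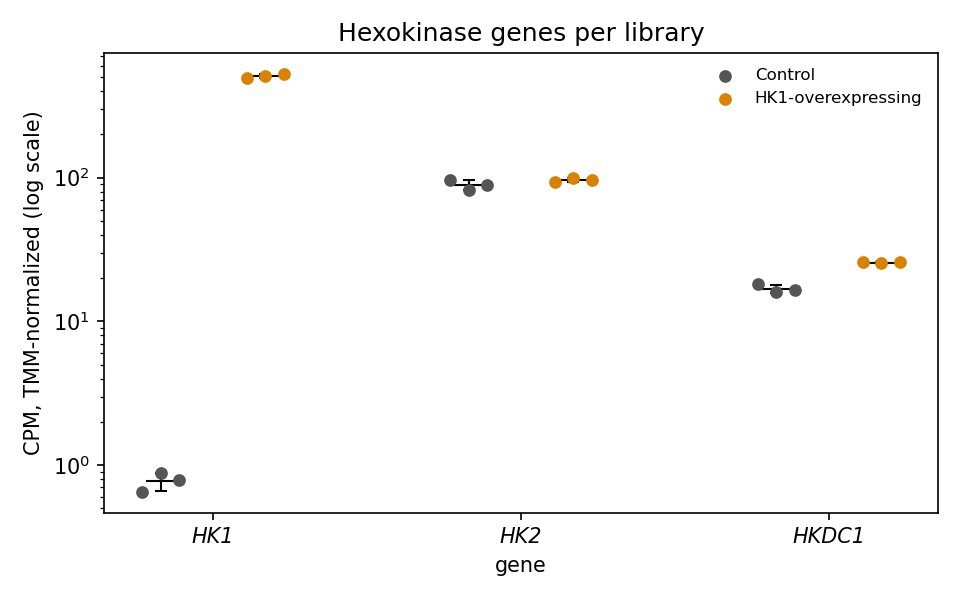
Level of each tested hexokinase gene in each library (y axis, CPM on a log scale) by gene (x axis), with points for libraries and black marks for the group mean ± SD (n = 3). HK1 is near 0.774 CPM in controls and 508.5 CPM in HK1-overexpressing cells, HKDC1 is higher in overexpressing cells, and HK2 overlaps in error.

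Beyond HK1, among called genes with a mean CPM of at least 10 and no overlap between groups, AHSG fell most and IGFL2-AS1 rose most, and some genes at lower levels changed by more. AHSG, which encodes the plasma protein fetuin-A, fell from 227.1 ± 7.33 to 90.7 ± 2.14 CPM (log2 -1.32, SE 0.0507). KNG1, kininogen, changed by -1.21, SLC38A3, an amino acid transporter, by -1.13, ITIH2 by -1.05, GC, the vitamin D-binding protein, by -1.04, SERPINC1, antithrombin, by -1.04, ASGR1, the asialoglycoprotein receptor, by -1.03, and MEP1A by -1.02 on the log2 scale. Among rises, AKR1B1, aldose reductase, went from 308.6 ± 18.2 to 576.4 ± 9.25 CPM (log2 0.90, SE 0.0511), and MYOF, a membrane repair protein, from 82.3 ± 7.58 to 160.4 ± 0.404 CPM (log2 0.96). IGFL2-AS1 rose by 1.16, PLCXD3 by 1.01, SP140 by 1.01, LRRN1 by 0.94, SH2D5 by 0.93, ETS1, a transcription factor, by 0.90, DKK1, a Wnt antagonist, by 0.87 and LUM, lumican, by 0.72. The counting used no strand, so IGFL2-AS1 cannot be told apart from transcription on the opposite strand. In all, 1342 of 16734 tested genes changed, 648 higher and 694 lower, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. All 1342 had no overlap between groups, which selection by p favours. Among all tested genes 27.8% had none. Chance gives 10% only where both groups vary alike. Control libraries varied more than overexpressing ones, so the 27.8% cannot be read against 10% as evidence of change. The median size of change of called genes was 0.348 on the log2 scale, and 48 genes, 32 higher and 16 lower, passed a test against a fold of 1.5. With library totals only in place of TMM, 898 genes were higher and 463 lower, so 66.0% were higher in place of 48.3%. The count rested on which libraries entered: 2257 without control replicate 1, 809 without control replicate 3, and 554, 536 and 598 without HK1-overexpressing replicate 1, 2 and 3. The 48 became 28 without control replicate 3, 30 without HK1-overexpressing replicate 2, 28 without HK1-overexpressing replicate 3 and 29 with a mean CPM of at least 5.

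**Figure D2:**
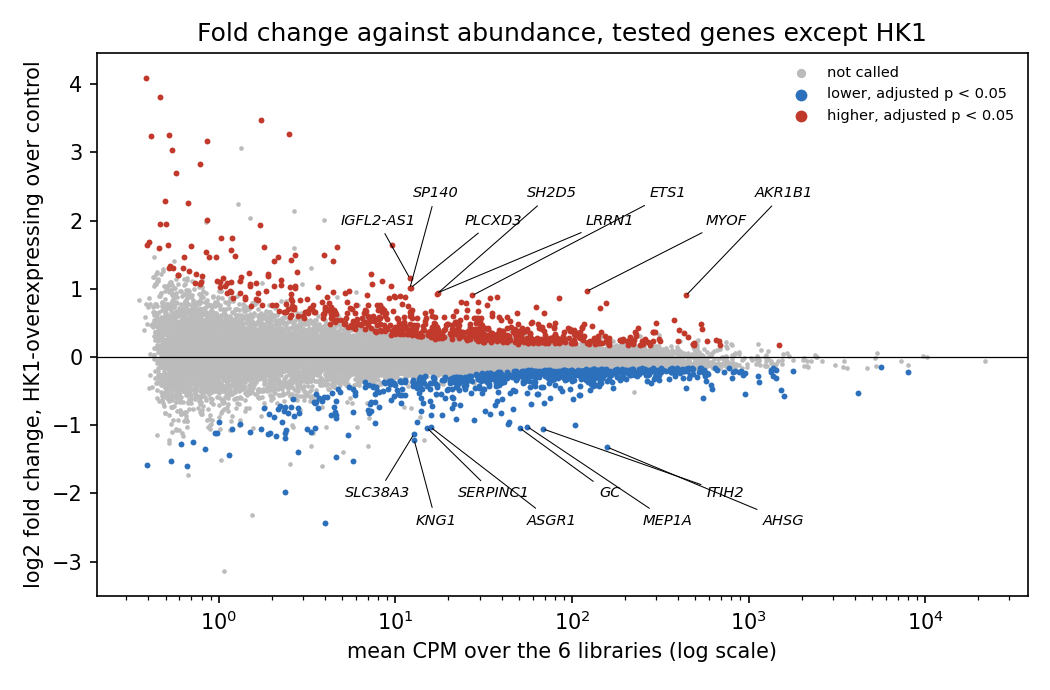
Log2 fold change of HK1-overexpressing over control cells (y axis) against mean CPM over the 6 libraries on a log scale (x axis), for tested genes except HK1. Red points are the called higher genes and blue points the 694 called lower genes, and grey points were not called. The naming rule's 8 largest rises and falls, among genes with a mean CPM of at least 10, are labelled.

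Genes for proteins that hepatocytes secrete were lower in HK1-overexpressing cells. Of 42 tested, 29 fell and 0 rose, or 35 and 0 when adjusted over the list alone, with a median log2 change of -0.50 (camera adjusted p = 2.73e-74, and adjusted p = 0.0181 with an estimated correlation). AHSG, KNG1 and ITIH2 are among them, and AFP, alpha-fetoprotein, fell from 1891 ± 32.1 to 1275 ± 37.2 CPM (log2 -0.57). Among 20 genes of the urea cycle and amino acid catabolism, 3 fell and 0 rose, with 6 falling when adjusted over the list alone (camera adjusted p = 4.83e-05, and adjusted p = 0.0765 with an estimated correlation). TAT, tyrosine aminotransferase, fell from 6.04 ± 0.534 to 3.23 ± 0.258 CPM. The falls numbered 5 without control replicate 2. Of 25 hepatocyte transcription factor genes, 7 fell and 1 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00577, and adjusted p = 0.312 with an estimated correlation). NR1H4, the bile acid receptor FXR, fell from 48.8 ± 1.69 to 32.0 ± 1.11 CPM. The list's call was lost without control replicate 1 (camera adjusted p = 0.0886), and its fallen genes numbered 1, 1 and 2 without HK1-overexpressing replicate 1, 2 and 3 and 3 without control replicate 3. Of 30 bile acid and drug metabolism genes 4 rose and 5 fell, or 6 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.697). Its median log2 change was -0.03 although camera's direction was upward.

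Genes of cell division were lower by small amounts. Of 46 G1/S genes 31 fell and 0 rose, or 38 and 0 adjusted over the list alone, with a median log2 change of -0.23 (camera adjusted p = 1.56e-26, and adjusted p = 0.0132 with an estimated correlation). Of 44 G2/M genes 18 fell and 0 rose, or 24 and 0 adjusted over the list alone (camera adjusted p = 3.26e-14, and adjusted p = 0.0181 with an estimated correlation). MCM7 and MCM3, parts of the replicative helicase, fell by 0.35 and 0.32 on the log2 scale, CDC45 fell by 0.41, and TOP2A, topoisomerase II alpha, fell by 0.34. PLK1, a mitotic kinase, fell by 0.31. The fallen G1/S genes numbered 15, 16 and 14 without HK1-overexpressing replicate 1, 2 and 3, and the fallen G2/M genes numbered 10 without any of them. Of 42 MYC target and ribosome biogenesis genes 10 fell and 0 rose, with 17 falling when adjusted over the list alone (camera adjusted p = 9.9e-08, and adjusted p = 0.103 with an estimated correlation). Those falls numbered 0 without any 1 HK1-overexpressing replicate, 2 without control replicate 3 and 16 without control replicate 1. Of 28 genes of glutamine and nucleotide synthesis 6 fell and 1 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00462, and adjusted p = 0.125 with an estimated correlation). CTPS1 and RRM2 of nucleotide synthesis fell by 0.30 and 0.26 on the log2 scale. The falls numbered 2 without control replicate 3 or any 1 HK1-overexpressing replicate. Of 74 cytosolic ribosomal protein genes 1 fell, and 0 did when adjusted over the list alone (camera adjusted p = 4.83e-05, and adjusted p = 0.633 with an estimated correlation). That list moved with the control libraries: its mean log2 CPM was 7.11, 7.41 and 7.31 in control replicates 1, 2 and 3 and 7.16 to 7.20 in overexpressing cells, 47 members fell without control replicate 1, and the call was lost without control replicate 2 (camera adjusted p = 0.168).

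Interferon-stimulated genes were higher in HK1-overexpressing cells. Of 32 tested, 14 rose and 0 fell, or 21 and 2 adjusted over the list alone, with a median log2 change of 0.29 (camera adjusted p = 9.74e-10, and adjusted p = 0.0201 with an estimated correlation). MX1, an antiviral GTPase, rose by 0.67 on the log2 scale, and PARP14 went from 67.4 ± 6.07 to 90.9 ± 4.17 CPM and ISG15 from 25.6 ± 3.18 to 34.6 ± 0.450 CPM. The rises numbered 9 without control replicate 3 and 8 and 9 without HK1-overexpressing replicate 1 and 2. Among 26 genes of NF-kB and the acute phase 4 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0082, and adjusted p = 0.141 with an estimated correlation). SOD2, mitochondrial superoxide dismutase, and TNFAIP3, an NF-kB inhibitor, rose by 0.48 and 0.39 on the log2 scale. The falls were of ORM1 and ORM2, near-identical acute phase genes whose counts are uncertain and whose calls were lost without some single libraries, among them HK1-overexpressing replicate 2 for ORM2 and replicate 1 for ORM1. The rises numbered 6 and 7 without control replicate 1 and 2, and 2 without HK1-overexpressing replicate 2 or 3. Of 10 antigen presentation genes 2 rose and the list was not called (camera adjusted p = 0.0756), although it was without HK1-overexpressing replicate 1 and without a filter (camera adjusted p = 0.0356 and 0.0425).

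Stress-related lists moved in different directions. Of 39 autophagy and lysosome genes 12 rose and 0 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.48e-06, and adjusted p = 0.125 with an estimated correlation). RRAGD, a lysosomal GTPase, rose by 0.28 on the log2 scale. The rises numbered 4, 1 and 2 without HK1-overexpressing replicate 1, 2 and 3. Of 24 hypoxia genes 7 rose and 2 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 2.41e-06, and adjusted p = 0.141 with an estimated correlation). BHLHE40, a transcription factor, rose by 0.42 on the log2 scale, and BNIP3L, a mitophagy receptor, rose by 0.34. The rises numbered 11 without control replicate 1 and 4 without any 1 HK1-overexpressing replicate. Of 35 genes of the integrated stress response 9 rose and 0 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 6.53e-04, and adjusted p = 0.159 with an estimated correlation). VLDLR and ADM2 rose by 0.68 and 0.70. The rises numbered 4 without control replicate 3 and 2 without any 1 HK1-overexpressing replicate. Of 29 genes of the unfolded protein response 5 fell and 1 rose, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.183 with an estimated correlation). HSPA5, the chaperone BiP, fell from 1576 ± 29.6 to 1278 ± 21.9 CPM. The list's call was lost with library totals only, a mean CPM of at least 5, without control replicate 1 and without each HK1-overexpressing replicate, where the largest camera adjusted p was 0.148. The falls numbered 8 without control replicate 1 or 2 and 2 without any 1 HK1-overexpressing replicate. Of 32 NRF2 target genes 4 fell and 2 rose, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.0224, and adjusted p = 0.141 with an estimated correlation). GPX2, a glutathione peroxidase, changed by -0.96 and HMOX1, heme oxygenase 1, by 0.28. That call was lost with library totals only, a mean CPM of at least 5 and without control replicate 2. The falls numbered 9 and 2 without control replicate 1 and 3, and 1, 1 and 2 without HK1-overexpressing replicate 1, 2 and 3.

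Among lists of glucose use other than the hexokinases, camera called the hexosamine pathway upward and ChREBP targets downward, neither with an estimated correlation. Of 20 glycolysis genes 3 rose and 0 fell, also 3 and 0 adjusted over the list alone, and the list was not called (camera adjusted p = 0.131), although it was without control replicate 2 and with the GC trend removed (camera adjusted p = 0.0249 and 0.0434). ENO2, an enolase, rose by 0.57 on the log2 scale. PFKP and PFKFB2 rose by 0.71 and 0.34 on the log2 scale, but each call was lost without control replicate 3 or any 1 HK1-overexpressing replicate. The call of PFKP was also lost without control replicate 1 and with DESeq2 (DESeq2 adjusted p = 0.131, the largest for PFKP), and that of PFKFB2 with a gene length or GC trend removed (its largest edgeR adjusted p was 0.145, without HK1-overexpressing replicate 1). Of 21 gluconeogenesis and glycogen genes 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, with a median log2 change of -0.00278 although camera's direction was upward (camera adjusted p = 0.774). PPP1R3B, which directs a phosphatase to glycogen, rose by 0.47 on the log2 scale. The rises and falls numbered 1 and 1 without control replicate 3 or HK1-overexpressing replicate 1, and 1 and 0 without HK1-overexpressing replicate 2 or 3. Of 10 genes of glucose and lactate transport 0 rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.883). The fall was of SLC5A9 (log2 -0.82) and was lost without control replicate 2 or 3 or any 1 HK1-overexpressing replicate. Of 12 pentose phosphate genes 1, TKT, fell (log2 -0.22), also 1 adjusted over the list alone (camera adjusted p = 0.118, and 0.0192 with DESeq2). The call of TKT was lost without HK1-overexpressing replicate 1 or 2. Of 13 hexosamine genes 1, OGA, rose (log2 0.23), and 4 did adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.305 with an estimated correlation). The rises numbered 3 and 4 without control replicate 1 and 2. OGA removes the sugar that this pathway supplies, and its call was lost without control replicate 3 or any 1 HK1-overexpressing replicate. The list's call was lost without control replicate 2, without HK1-overexpressing replicate 2 and with the GC trend removed, where the largest camera adjusted p was 0.0864. Of 11 ChREBP targets 3 fell and 0 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00853, and adjusted p = 0.141 with an estimated correlation). KHK, ketohexokinase, fell from 8.95 ± 0.736 to 5.66 ± 0.744 CPM. The falls numbered 2 without control replicate 3 or HK1-overexpressing replicate 3, and 1 without HK1-overexpressing replicate 1 or 2. The call was lost with a mean CPM of at least 5 (camera adjusted p = 0.0547). None of 75 nuclear OXPHOS subunit genes and none of 13 mitochondrially encoded mRNAs was called by edgeR (camera adjusted p = 0.369 and 0.104), by DESeq2 or by limma-voom without quality weights. At an unadjusted edgeR p below 0.05, 1 of the former was higher and 1 lower, and 0 and 3 of the latter. Without control replicate 1, 8 and 7 of them fell (camera adjusted p = 5.7e-06 and 0.000214). Camera also called both lists with DESeq2 (adjusted p = 0.0415 and 0.00071), and the mitochondrially encoded mRNAs without a filter, with quality weights, where 3 fell, and with the GC trend removed. The mean log2 CPM of the OXPHOS genes was 6.02, 6.27 and 6.24 in control replicates 1, 2 and 3 and 6.15 to 6.17 in overexpressing cells, and that of the mitochondrially encoded mRNAs was 11.7, 11.9 and 11.9 and 11.7 to 11.8.

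Of 35 TGF-beta and EMT genes 8 rose and 4 fell, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.00421, and adjusted p = 0.141 with an estimated correlation). LAMA3, a laminin chain, and TAGLN, transgelin, rose by 0.47 and 0.67 on the log2 scale, and SMAD6, a signalling inhibitor, fell by 0.49. The rises numbered 5 without control replicate 3 or any 1 HK1-overexpressing replicate. Among markers of cell types other than hepatocytes, 3 of 9 fibroblast and stellate cell markers rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.189 with an estimated correlation). LUM and COL1A2 are among the rises, while LOX fell, a call lost without control replicate 3 or HK1-overexpressing replicate 1 or 2. The list's median log2 change was -0.03 although camera's direction was upward. Its call was lost without HK1-overexpressing replicate 3 (camera adjusted p = 0.145). Of 5 endothelial, 3 leukocyte and 7 kidney packaging-line markers, 1, 0 and 1 rose and 0, 1 and 0 fell, and no such list was called (camera adjusted p = 0.374, 0.104 and 0.372). In all, camera called 20 of 46 lists, 9 upward and 11 downward. The 4 that held with an estimated correlation were hepatocyte secreted proteins, G1/S genes, G2/M genes and interferon-stimulated genes. A call lost there does not by itself show that the genes are correlated. The estimated correlation was below the preset 0.01 for ChREBP targets (-0.0829) and the urea cycle list (-0.0393), which lost their calls. For G1/S genes it was 0.0052, yet camera's unadjusted p went from 6.77e-28 to 0.000287. For these lists the larger p cannot come from a correlation above the preset, so the settings differ in more than that. Fry's directional test called 25 lists, but not cytosolic ribosomal proteins or hepatocyte transcription factors (fry adjusted p = 0.344 and 0.0587).

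**Figure D3:**
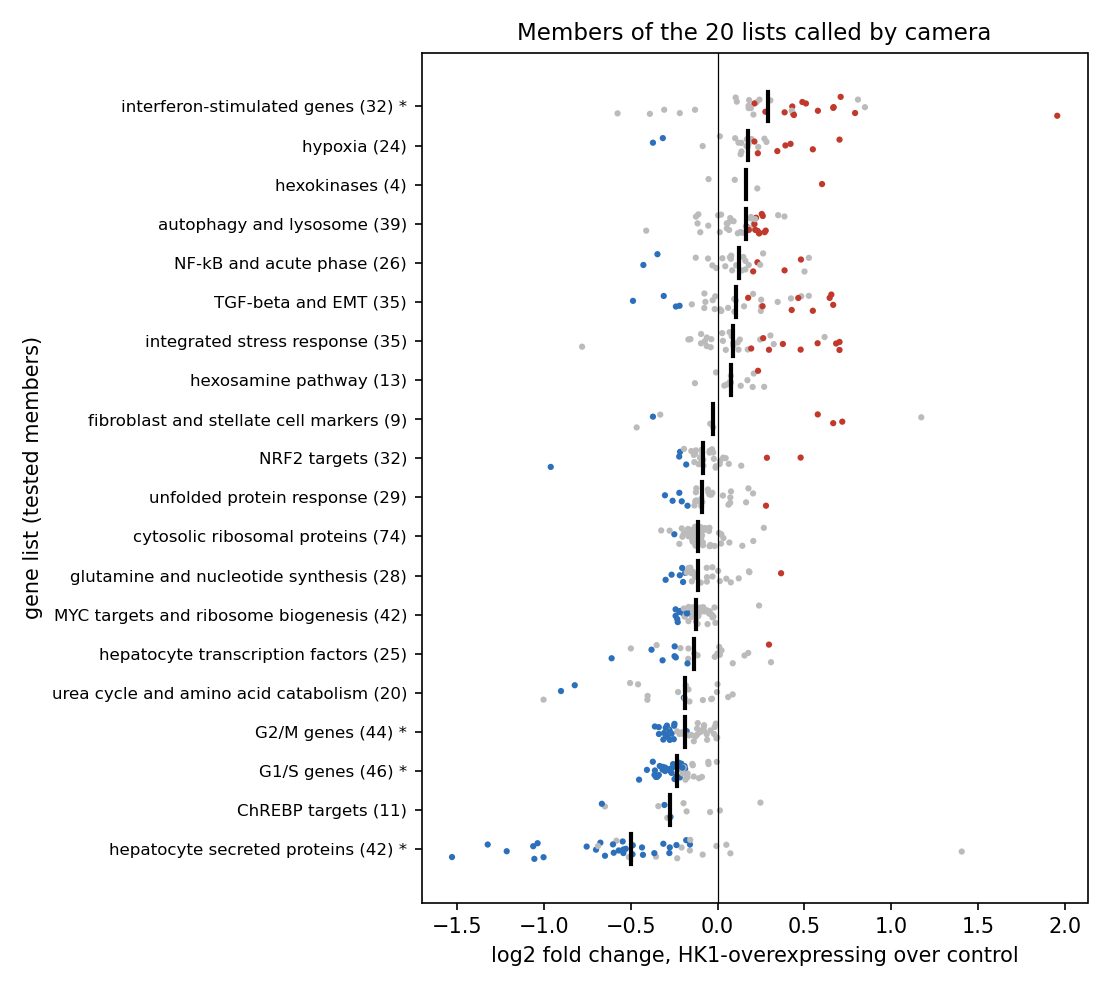
Log2 fold change of HK1-overexpressing over control cells (x axis) for each tested member of the 20 lists called by camera (y axis, with the number of tested members), where red and blue points are called higher and lower genes, grey points are not called and the black bar is the median. An asterisk marks the 4 lists that held with an estimated correlation, and the hepatocyte secreted proteins have the lowest median, -0.50.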

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

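HK1 stayed higher past the threshold in the 19 refitted alternatives that kept its reads; removing them left no value for it. Of 133 named genes, 90 kept their direction and side of the threshold in every alternative that gave them a value. Some of the 90 lacked a value in some settings, such as CYP2C8, which had one in 19 of 20. The cause was not tested for the changes below, except that leaving out samples or genes leaves fewer of them. Genes changed numbered 1342, and 2155 (1018 higher, 1137 lower) with quality weights, an alternative chosen after seeing the data, as was the GC trend. At an adjusted p below 0.01 there were 574 (289 and 285). Leaving out each replicate gave 536 to 2257 genes (286 to 1172 higher, 250 to 1085 lower). Library totals only gave 66.0% higher calls where TMM gave 48.3%. Genes changed at least 1.5-fold numbered 48, and 29 with a mean CPM of at least 5, 227 against a fold of 1.2, 7 against a fold of 2, and 28 to 53 leaving out each replicate. Lists called numbered 20, and 4 with an estimated correlation, 25 by fry's directional test, 39 by fry's mixed test, and 18 to 21 leaving out each replicate. The gap between groups on the first principal component was 19.3 (SD 2.82), and 16.6 (SD 3.88) with HK1 reads removed. It was 19.1 to 21 leaving out each replicate, where the SD was 0.663 without control replicate 2 and up to 3.92 otherwise.

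The replicate numbers do not pair the samples: deviations of same-numbered samples correlated at -0.03, 0.054 and -0.197 across genes, and not every sample correlated best with its own number (control replicate 1 did with HK1-overexpressing replicate 3, at 0.093). With the replicate block 1074 genes were called. The block with a length correction was not run because the numbers do not pair the samples.

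No called list changed direction. Lists uncalled both in the reported test and in the setting named changed camera's direction, with these medians on the log2 scale, given as the range over leaving out each replicate where such a setting did so. For glucose and lactate transport they were 0.0324 without a filter, 0.015 with DESeq2, and -0.0162 to 0.0858 leaving out each replicate. For biliary and progenitor markers they were 0.0281 with DESeq2, 0.0376 with limma-voom, 0.0309 to 0.1 leaving out each replicate, 0.0285 with quality weights and 0.0422 with the GC trend removed. For nuclear OXPHOS subunits and for gluconeogenesis and glycogen they were -0.0933 to 0.0344 and -0.0232 to 0.0117 leaving out each replicate. For bile acid and drug metabolism it was -0.037 to 0.0332 leaving out each replicate. Depth limits HK3, which had a count of 0 in every library.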

Other observations

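The tests of chromosomes 9 and 10 were chosen only after the result was seen, and took the place of a weighing of the lower cell division genes and of neighbouring genes that was planned before the data were examined and not carried out. The genes in this paragraph that are outside the naming rule, SAMD3, SLFN11, SLC6A11, F13B, CAV1, NRP2, LOXL2, APOA2 and ASGR2, were chosen after their values were seen. Some of the largest changes were at low levels. CYP2C8, a drug-metabolising cytochrome P450, rose from 0.472 ± 0.0720 to 4.56 ± 0.503 CPM, SAMD3 from 0.282 ± 0.0607 to 3.18 ± 0.0978 CPM and SLFN11 rose by 1.61 on the log2 scale (SD, n = 3 each). SLC6A11, a GABA transporter, fell from 6.77 ± 0.833 to 1.24 ± 0.335 CPM and F13B, a coagulation factor subunit, from 8.57 ± 0.808 to 2.97 ± 0.143 CPM. At higher levels CAV1, caveolin, rose by 0.89 on the log2 scale, NRP2 by 0.81 and LOXL2, a lysyl oxidase, by 0.73, while APOA2, an apolipoprotein, fell by 1.00 and ASGR2 by 0.99.

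Several lists that camera did not call held members that moved both ways. Of 18 biliary and progenitor markers 2 rose and 3 fell: CD44 rose by 0.44 and SPP1, osteopontin, by 0.36 on the log2 scale, while GPC3, glypican 3, fell by 0.45 and ALDH1A1 by 0.28. Of 40 growth factor and immediate early genes 7 rose and 6 fell. FGFR3 and FGFR4, fibroblast growth factor receptors, fell by 0.46 and 0.39 and IGF2 by 0.71, while IGFBP1 rose by 0.91. Among bile acid and drug metabolism genes, CYP1B1 and SULT2A1 rose by 0.81 and 0.39, and UGT2B4, whose family members share sequence, fell by 0.68. Of 28 genes of fatty acid oxidation 2 rose and 3 fell, with CPT1A higher by 0.28 and FABP1, a fatty acid binding protein, lower (log2 -0.84).

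The 1342 genes called in the real split of the 6 samples compare with at most 2 in the 9 other splits of 3 against 3. Each of those 9 has libraries of both groups on each side, so the group difference enters its residual spread and holds calls down. Their low counts therefore decide nothing. The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

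The lower hepatocyte secreted protein genes were set against technical explanations. A copy-number difference would lower neighbouring genes too, but the median of other genes within 5 Mb was -0.00348 (bootstrap spread 0.011). With a trend on GC content and exon length taken off the list's median was -0.498 (spread 0.061), where it was -0.50 before. The groups differed by 4.49 times the range of the control libraries in the list's mean log2 CPM, which leaves a difference in culture state open, since the labels do not say that replicates were separate cultures and their range may be technical. A response to HK1 and a difference in how the cell populations were derived also stay open and were not tested.

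The rise of HKDC1 was tested against assignment of HK1 fragments to it, which would need 1.73% of HK1 fragments. By alignment, 0% of 3899 windows of 100 bases of an HK1 transcript matched HKDC1 at 95% identity, and the highest identity was 86%. Why HKDC1 rose was not tested otherwise.

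Genes on chromosome 10 were slightly higher and genes on chromosome 9 slightly lower, found by looking over 23 chromosomes. With a GC content and length trend taken off, the medians were 0.0476 (spread 0.008) and -0.0602 (spread 0.0061), so that trend is not the whole cause, although the libraries' deviations from their group means followed GC content by different amounts (Spearman -0.511 to 0.598 across genes, which are not independent). For genes that were not called, 10000 shuffles of genes gave a Bonferroni-corrected share of 0.0023 for each chromosome, the smallest they can give, but these chromosomes were picked as extremes and shuffles treat neighbouring genes as independent, so this decides nothing about copy number. Medians of 10 Mb windows were uneven. They were above 0 in 11 of 14 on chromosome 10 (-0.072 to 0.12) and below 0 in 8 of 10 on chromosome 9 (-0.123 to 0.101). With the trend taken off, most chromosomes had a median below 0, among them chromosome 1 at -0.0377 and chromosome 22 at -0.0342. Windows below 0 are therefore not particular to chromosome 9. Before the correction the median was -0.0608 for chromosome 9 and -0.0593 for chromosome 22. A copy-number difference in part of the cells and coordinated regulation stay open.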
